A study of Mus musculus with 6 samples.

How the data were processed

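Whole adrenal glands of C57BL/6 mice were compared 3 h after saline or LPS, with 3 libraries per group. Per the labels' protocols, attached fat and connective tissue were removed, total RNA was isolated on columns, RNA integrity was checked, cDNA was amplified with a SMARTer Ultra kit, and libraries were made with NEBNext Ultra chemistry and sequenced from a single end on an Illumina instrument. The protocols name no strand-specific step and the strand setting of the counting is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. The LPS dose and the route of injection are not given in the sources used here.

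The deposited table holds raw read counts per Ensembl gene for the 6 libraries. Per the submitters' processing notes, Trim Galore, HISAT2, HISAT and HTSeq were used with the mm10 build, with no versions or settings given; the annotation release is not given in the sources used here. The table has 15317 genes, and in each the second-highest library is at 1.0057 CPM or more, so the authors' counts were limited to genes at more than 1 CPM in 2 or more libraries. The authors' deposited table also gives, per the file headers, a log2 fold change and a log2 average abundance for each gene, the common and the gene-wise dispersion, p-values and adjusted p-values with each, and a call coded as a score of 1, 0 or -1. The file does not name the tool behind that comparison. These columns were used only for the comparison with the calls made here. Gene symbols and positions were taken from GENCODE M21 on the same build by Ensembl identifier; 15270 identifiers matched and 47 did not, and the latter were tested without a symbol.

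Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 15248 genes and removed 69. Libraries were scaled with TMM factors, which were 1.239 to 1.281 for saline and 0.7854 to 0.7979 for LPS. The groups' factors did not overlap. Fold changes are relative to the bulk of genes and do not measure the absolute amount of RNA. Dispersions were estimated with robust settings, and a quasi-likelihood F test was made for LPS against saline with no other term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error is the absolute log2 change divided by the square root of the F statistic. CPM values use the TMM factors unless total counts are named, and their spread is an SD over 3 libraries. For a gene with 0 counts in a group the fold is a lower bound against 3 counts over that group, and with 1 to 3 counts it is the ratio with an exact 95% interval; these cover counting error only.

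Gene lists, 24 for processes and 14 for cell types or zones, were written before the data file was opened, as were the tests, the alternatives and the rule for named genes. Lists with 3 or more tested members were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists, with camera at an estimated correlation, and with fry. Named genes were the 6 largest rises and 6 largest falls among called genes with at least 5 CPM in the higher group, a standard symbol and no overlap between groups; for each list up to 4 called members with the largest change and up to 2 that moved against the majority, or 2 with the smallest adjusted p where none was called; and 10 genes fixed by name, which were Star, Cyp11a1, Cyp11b1, Cyp11b2, Mc2r, Th, Pnmt, Tnf, Il1b and Il6. Some genes named by the lists alone are not reported here. Measures of library composition were compared with an exact two-sided permutation test, whose smallest p is 0.1.

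The procedure was tested on simulated counts drawn for the same 15248 genes and library sizes with 200 changed genes. edgeR recovered 14.93% of genes changed 1.5-fold, 62.69% of those changed 2-fold and 86.36% of those changed 4-fold, with 9 false calls. DESeq2 1.42.0 recovered 26.87%, 64.18% and 87.88% with 34 false calls, and limma-voom (limma 3.58.1) 11.94%, 53.73% and 87.88% with 5. A simulated list of 25 genes raised 1.5-fold was called by all 3 list tests, and of 20 unchanged lists camera called 0 with either correlation and fry called 1. The simulated genes were drawn independently, whereas the estimated correlation within the real lists reached 0.49 (cholesterol synthesis). The simulation therefore does not test the list tests on correlated genes. With 200 changed genes against 8512 called in the data, it also does not give the rate of false calls there. Within groups, log2 CPM correlated at 0.9664 to 0.9793 across genes and no 2 libraries agreed within sampling noise, the lowest chi-square per gene being 14.97.

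The alternatives were median-ratio and upper-quartile factors, total counts only, no expression filter, a filter of at least 1 CPM in 3 or more samples, DESeq2, limma-voom, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, and scaling without the 20 most abundant genes. Without the genes held by more than 1 list, 35 lists were tested again. The zona fasciculata list was not, as it had fewer than 3 tested members left.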

Results

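The acute response of the mouse adrenal gland to endotoxin was profiled by RNA sequencing of whole glands. Wild-type C57BL/6 mice aged 8 weeks received saline or bacterial lipopolysaccharide (LPS), the outer-membrane glycolipid that activates Toll-like receptor signalling, and glands were collected after 3 h. There were 3 saline and 3 LPS libraries. Their gene counts summed to 22593569, 17578086 and 23864796 for saline replicates 1, 2 and 3, and to 28156666, 20578371 and 19297984 for LPS replicates 1, 2 and 3. Mean depth was 21345484 counts for saline and 22677674 for LPS (exact permutation test, two-sided, p = 0.8, with 0.1 as the smallest p that 3 against 3 allows). The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries, which may be partly technical. Fold changes below are log2 values of LPS over saline ± standard error (SE) from edgeR's quasi-likelihood fit with n = 3 per group, and adjusted p-values are Benjamini-Hochberg values from that fit unless another test is named. Gene positions are those of the mm10 build in the GENCODE M21 annotation.

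The question was which transcripts changed in the gland within 3 h of LPS. Cytokine, chemokine and interferon-stimulated transcripts were among those that rose most. Genes of steroid hormone production moved both ways by smaller factors, as did markers of endothelial and stromal cells, of which more fell than rose. Of 15248 genes tested, 4198 were higher and 4314 lower with LPS, which together were 55.82% of the genes. By at least 2-fold, 2277 genes were higher and 2574 lower. The first principal component carried 80.77% of the variance and separated the groups, and 9464 of the 15248 genes had no overlap between the groups' values, where chance gives 10% of genes for 3 against 3. The split between directions depended on scaling: with libraries scaled to total counts only, 1973 genes were higher and 8992 lower (17.99% higher, against 49.32% with TMM factors), and with upper-quartile factors 3331 were higher and 5511 lower (37.67% higher). Total-count scaling moved the median log2 change of all genes by -0.67 and upper-quartile scaling by -0.19, so every direction below is relative to the bulk of genes.

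Lists of immune genes took a larger share of the LPS libraries. The share of the interferon-stimulated list rose from 0.153% ± 0.012 to 6.13% ± 0.87, and that of the chemokine list from 0.0265% ± 0.0012 to 0.982% ± 0.132 (SD, n = 3; exact permutation p = 0.1 for each). The median gene had 17.1 ± 0.4 CPM (counts scaled to a common library size, here by total counts) in saline and 9.86 ± 0.17 in LPS (SD, n = 3). The 20 most abundant genes held 18.4% ± 0.7 of counts in saline and 20.5% ± 0.5 in LPS (SD, n = 3; exact permutation p = 0.1), a difference of 2.09 percentage points that was 4.80 without mitochondrially encoded genes and 6.43 for the 100 most abundant genes. By contrast, the mitochondrially encoded share, 8.69% ± 0.80 and 7.25% ± 0.60, overlapped between groups (SD, n = 3; exact permutation p = 0.2).

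The 6 largest rises by fitted log2 change, among genes with at least 5 CPM in LPS and no overlap between groups, were dominated by immune mediators. Cxcl11, an interferon-inducible chemokine gene that the annotation lists as a polymorphic pseudogene (chromosome 5, 92359544 to 92365485), had 0 counts in the saline libraries and 3165 in the LPS libraries, at least 1574-fold higher against a floor of 3 counts over the group. Il27, encoding an interleukin subunit, went from 0 to 2204 counts, at least 1096-fold higher, and the potassium channel gene Kcnk10 from 0 to 703 counts, at least 349.7-fold higher. By these bounds Cxcl11, Il27 and Kcnk10 lie below Il1rn, which rose 2118-fold by the fit, so their places rest on fitted values. Cxcl5, a neutrophil attractant, had 1 count in saline and 4001 in LPS, a ratio of 5970 (95% counting interval 1071 to 235900). Il6 (chromosome 5, 30013114 to 30019981) rose by 11.65 ± 0.28 to 217 ± 15 CPM (SD, n = 3). Cxcl10 (chromosome 5, 92346638 to 92348889) rose by 11.13 ± 0.38, from 2.47 ± 1.59 to 5280 ± 1356 CPM (SD, n = 3). Floors and intervals cover counting error only.

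The 6 largest falls among genes with at least 5 CPM in saline and no overlap between groups were Map2k6, Thsd1, Klhl14, Samd10, Pcdh12 and Exoc3l2. Map2k6, encoding a kinase upstream of p38, had 444 counts in saline and 1 in LPS, 297.6-fold lower (95% counting interval 53.13 to 11780). Klhl14 (chromosome 18, 21550377 to 21654718) fell by 4.93 ± 0.22, from 57.2 ± 5.6 to 1.84 ± 0.18 CPM (SD, n = 3). Thsd1 fell by 4.99 ± 0.53. Pcdh12, a protocadherin gene of endothelial cells, fell by 4.60 ± 0.40, from 12.7 ± 1.1 to 0.457 ± 0.441 CPM (SD, n = 3). Samd10 fell by 4.74 ± 0.28 and Exoc3l2 by 4.51 ± 0.37. These 6 genes had adjusted p between 7.4e-12 and 5.7e-06.

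Every measured cytokine gene rose: 21 of 21, with a median log2 change of 5.28 (38.8-fold). The list held 25 genes. Genes near 0 in saline were in the deposited counts only where LPS raised them, so this count and median are partly set by the authors' filter. Tnf (chromosome 17, 35199381 to 35202007) rose by 8.59 ± 0.42 to 30.9 ± 5.0 CPM (SD, n = 3), Il1b by 3.79 ± 0.32, Csf3, the neutrophil growth factor, by 10.47 ± 0.41, and Il1rn, the interleukin-1 receptor antagonist, by 11.05 ± 0.26. Of 27 chemokine genes 23 rose and 2 fell, with a median of 6.00, or 5.40 with the 3 genes that had a group at 0 set to their bounds. Ccl2, the monocyte attractant, rose by 9.77 ± 0.20 to 2938 CPM, and Cxcl12, a homeostatic chemokine, fell by 0.92 ± 0.15. Both lists passed camera, a competitive test of a list against all other genes (adjusted p = 5.9e-31 for cytokines and 5.3e-34 for chemokines), and passed it with an estimated correlation between genes (adjusted p = 0.0037 and 0.010).

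Interferon-stimulated genes rose in 43 of 43 cases, with a median of 5.47. Ifit1 and Ifit2, antiviral RNA-binding proteins, rose by 8.58 ± 0.20 and 7.83 ± 0.21, and Oasl1 by 9.01 ± 0.24. Ifit1 reached 13110 CPM. The list passed camera (adjusted p = 6.5e-148, and 0.0037 with an estimated correlation). All 29 genes of NF-kB feedback and signalling rose, with a median of 3.71 (camera adjusted p = 2.1e-34, and 0.028 with an estimated correlation). Tnfaip3, a deubiquitinase that restrains the pathway, rose by 5.91 ± 0.20 and Ptgs2, the inducible prostaglandin synthase, by 6.28 ± 0.26. Among 23 antigen presentation genes 20 rose and 1, H2-DMa, fell by 0.87 ± 0.16. Cd274, encoding the checkpoint ligand PD-L1, rose by 7.74 ± 0.24 and Nlrc5, the class I transactivator, by 5.60 ± 0.17. This list had a median of 2.74 and a camera adjusted p of 2.3e-24, but adjusted p = 0.060 with an estimated correlation.

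Acute-phase and antimicrobial genes rose in 24 of 27 cases (median 5.02, camera adjusted p = 4.8e-29, and 0.010 with an estimated correlation). Lcn2, an iron-scavenging lipocalin, rose by 9.37 ± 0.25, Saa3 by 9.22 ± 0.60, and Acod1, which makes itaconate, by 10.90 ± 0.40. This list shares 4 genes with the neutrophil markers, which also rose, 16 of 16 with a median of 6.04. In the LPS recognition list 15 of 21 genes rose and none fell (16 adjusted over the list alone; median 1.80, camera adjusted p = 3.7e-10, and 0.032 with an estimated correlation); with total-count scaling 14 rose and 3 fell. Casp4, the intracellular LPS sensor also known as caspase-11, rose by 6.04 ± 0.20 and Tlr2 by 4.71 ± 0.23. Of 26 apoptosis and cell death genes 18 rose and none fell (20 adjusted over the list alone; median 1.84, camera adjusted p = 5.6e-12, and 0.024 with an estimated correlation), although 5 fell with total-count scaling. Mlkl, the executor of necroptosis, rose by 5.23 ± 0.15 and Cdkn1a by 4.49 ± 0.16.

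Vascular genes moved in both directions. Of 19 endothelial activation genes 13 rose and 3 fell (median 3.46, camera adjusted p = 1.1e-15, and 0.010 with an estimated correlation). Selp, encoding P-selectin, rose by 9.17 ± 0.32 and Ch25h by 6.30 ± 0.21, whereas Ednrb fell by 1.29 ± 0.25 and Plvap, of the fenestral diaphragm, by 1.11 ± 0.26. In the coagulation and fibrinolysis list 16 of 21 rose and none fell (median 2.40, camera adjusted p = 5.6e-12, and 0.010 with an estimated correlation), though 4 fell with total-count scaling. Procr, the endothelial protein C receptor, rose by 5.64 ± 0.19 and F10, encoding coagulation factor X, by 5.21 ± 0.55. The 21 endothelial markers instead included 12 that fell and 3 that rose, with a median of -0.74 (camera adjusted p = 0.014, and 0.19 with an estimated correlation). Sox17 fell by 5.06 ± 0.72, Tek, the angiopoietin receptor, by 2.70 ± 0.20 and Ptprb by 2.01 ± 0.16. Robo4 rose by 2.55 ± 0.13 and Cdh5, encoding VE-cadherin, by 1.33 ± 0.12, also under every other scaling, while Flt1 rose by 0.44 ± 0.12 with TMM but was not called with upper-quartile factors (adjusted p = 0.086) and lay at -0.23 with total-count scaling.

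**Figure D1:**
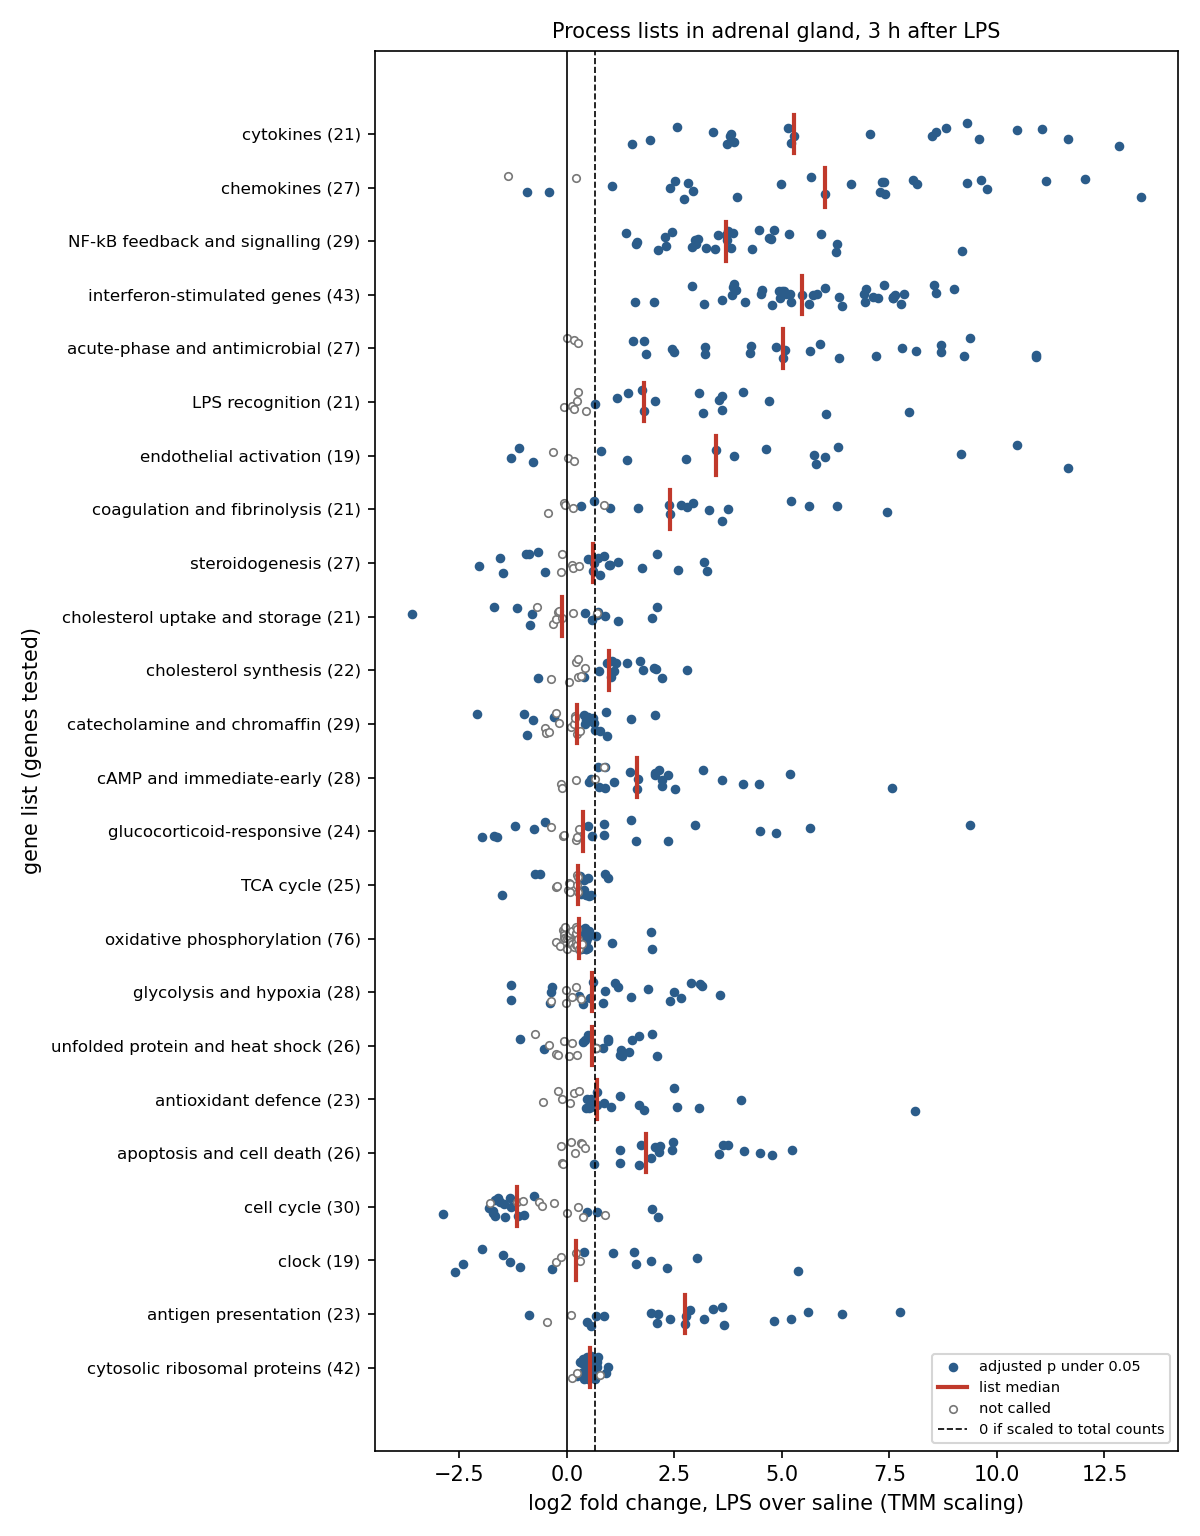
Log2 fold change of LPS over saline (x axis) for each tested member of the 24 process lists (rows, with the number of genes tested), as filled points where the adjusted p was under 0.05 and open points otherwise; red bars are list medians, and the dashed line marks where 0 lies with total-count scaling, a shift of 0.67. Cytokines, chemokines and interferon-stimulated genes had medians of 5.28, 6.00 and 5.47, whereas the oxidative phosphorylation and ribosomal protein medians, 0.29 and 0.55, lie left of the dashed line and so turn negative with that scaling; fitted values of the 3 chemokine and 3 cytokine genes with a group at 0 are no bounds.

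Transcripts of the steroid-producing cortex stayed abundant and several rose. Star, whose product brings cholesterol into mitochondria (chromosome 8, 25806555 to 25815982), rose by 1.00 ± 0.11, from 15400 ± 2049 to 30860 ± 3164 CPM (SD, n = 3; adjusted p = 1.1e-06). Cyp11a1, the side-chain cleavage enzyme (chromosome 9, 58006411 to 58027023), rose by 0.98 ± 0.12 (adjusted p = 2.7e-06). With TMM factors both were higher in all 3 LPS libraries than in any saline library. With total-count scaling the rises were 0.34 and 0.32 (adjusted p = 0.0071 and 0.016), and the Cyp11a1 values of the groups overlapped. Cyp11b1, the final enzyme of corticosterone synthesis, rose by 0.73 ± 0.13 (adjusted p = 0.00012) but by 0.06 with total-count scaling, which was no longer a call (adjusted p = 0.64). Cyp11b2, the aldosterone synthase (chromosome 15, 74851010 to 74856318), rose by 2.09 ± 0.19, from 162 ± 47 to 688 ± 93 CPM (SD, n = 3). Cyp11b1 and Cyp11b2 are close paralogs, as are Hsd3b1 and Hsd3b6, so the division of reads within each pair is uncertain.

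The corticotropin receptor gene Mc2r was at 371 ± 39 CPM in saline and 345 ± 44 in LPS (SD, n = 3), a log2 change of -0.10 ± 0.12 that was not called (adjusted p = 0.46). It was called lower with upper-quartile factors (-0.30, adjusted p = 0.034) and with total-count scaling (-0.77, adjusted p = 1.3e-05). Its accessory protein gene Mrap rose by 3.26 ± 0.13 and Akr1b7, an aldose reductase-like gene of the fasciculata, by 3.20 ± 0.15. Por, the electron donor of microsomal P450 enzymes, rose by 2.58 ± 0.11. Srd5a1, a steroid 5-alpha-reductase, fell by 2.03 ± 0.19, Hsd3b6 by 1.55 ± 0.17 and Hsd3b1 by 0.50 ± 0.10. In the steroidogenesis list as a whole 15 of 27 genes rose and 7 fell, with a median of 0.61, while with total-count scaling 8 rose and 11 fell, with a median of -0.06. The list passed camera (adjusted p = 0.033) but not with an estimated correlation (adjusted p = 0.38), with upper-quartile factors (0.056) or total-count scaling (0.24), without saline replicate 2 (0.062), or without the genes it shares with other lists (0.91).

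Markers of the cortical zones were taken as separate lists. Of 12 zona fasciculata markers 8 rose and 2 fell (9 and 2 adjusted over the list alone; median 0.87, camera adjusted p = 4.2e-05, and 0.16 with an estimated correlation), and with total-count scaling 6 rose and 4 fell. Scarb1 rose by 2.09 ± 0.10 and Frrs1 fell by 0.96 ± 0.21. Of 14 zona glomerulosa markers 7 fell and 2 rose, with a median of -0.29, against 11 and 1 with total-count scaling (median -0.96). The list missed the camera threshold (adjusted p = 0.066, and 0.38 with an estimated correlation) but passed without shared genes (0.026) and with total-count scaling (0.046). Shh, encoding the hedgehog ligand made by glomerulosa cells, fell by 3.45 ± 0.22 and Wnt4 by 2.15 ± 0.14, while Cyp11b2 rose. Among 4 measured markers of the X-zone, the inner cortical layer of young mice, Thrb fell by 1.45 ± 0.19 and Abcb1b by 0.63 ± 0.13 (camera adjusted p = 0.33). These lists share genes with the steroidogenesis list. Of the zona fasciculata list only Frrs1 was in no other list. Its camera result is therefore no separate support, and it could not be tested without shared genes.

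**Figure D2:**
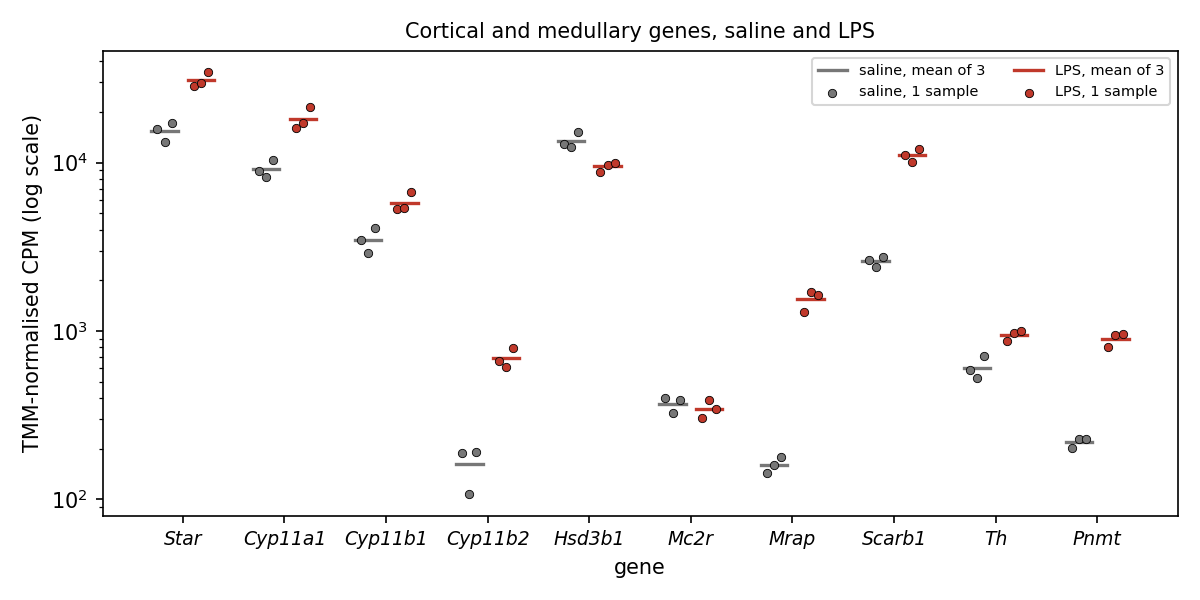
TMM-normalised CPM (y axis, log scale) of 10 cortical and medullary genes (x axis) in the 3 saline (grey) and 3 LPS (red) samples; points are single samples and bars are means. Star, Cyp11a1, Cyp11b1, Cyp11b2, Mrap, Scarb1, Th and Pnmt are higher in LPS on this scale and Hsd3b1 is lower, while Mc2r overlaps, at 371 and 345 CPM; with total-count scaling Th lies at a log2 change of -0.01 and Cyp11b1 at 0.06.

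Cells of the cortex draw cholesterol from synthesis, uptake and stores. In the synthesis list 14 of 22 genes rose and 1, Mvk, fell by 0.67 ± 0.18 (median 0.98, camera adjusted p = 0.00079, and 0.43 with an estimated correlation), and with total-count scaling 11 rose and 6 fell. Idi1 rose by 2.80 ± 0.18, Cyp51, a sterol demethylase, by 2.22 ± 0.19 and Hsd17b7 by 2.08 ± 0.20. Of 21 uptake and storage genes 8 rose and 5 fell, with a median of -0.11 and no difference from other genes by camera (adjusted p = 0.96); with total-count scaling 3 rose and 12 fell. Scarb1, the receptor for high-density lipoprotein, rose by 2.09 ± 0.10. Osbpl3, encoding an oxysterol-binding protein relative, fell by 3.60 ± 0.16 and Nceh1, a cholesteryl ester hydrolase, by 1.16 ± 0.14.

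Among genes listed for the medulla, Pnmt (chromosome 11, 98386450 to 98388181) encodes the enzyme that converts noradrenaline to adrenaline. Pnmt rose by 2.04 ± 0.11, from 219 ± 15 to 901 ± 88 CPM (SD, n = 3, adjusted p = 9.8e-11). Th, the first enzyme of catecholamine synthesis (chromosome 7, 142892752 to 142931128), rose by 0.65 ± 0.11 with TMM (adjusted p = 0.00015) but lay at -0.01 with total-count scaling. Gch1, which supplies the Th cofactor, rose from 28.22 ± 2.87 to 79.39 ± 15.02 CPM (SD, n = 3, adjusted p = 4.4e-07), and Gata3, a transcription factor of chromaffin cells, fell by 0.92 ± 0.16. Of 29 chromaffin genes 13 rose and 5 fell, with a median of 0.24, whereas 3 rose and 15 fell with total-count scaling. The list did not pass camera (adjusted p = 0.37). RNA of whole glands does not show in which cells these genes, Gch1 among them, changed.

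Genes that respond to cAMP and to glucocorticoids were followed as well. Of 28 cAMP and immediate-early genes 23 rose and none fell (median 1.64, camera adjusted p = 1.1e-10, and 0.21 with an estimated correlation), against 15 and 3 with total-count scaling. Fosl1 rose by 7.56 ± 0.32, Atf3 by 5.18 ± 0.25 and Pde4b, a cAMP phosphodiesterase, by 4.10 ± 0.15. In the glucocorticoid-responsive list 12 of 24 rose and 6 fell (median 0.38, camera adjusted p = 0.00019, and 0.039 with an estimated correlation), against 8 and 11 with total-count scaling. The metallothionein genes Mt1 and Mt2 rose by 4.86 ± 0.15 and 5.67 ± 0.14, and Arrdc2 fell by 1.97 ± 0.45. Without the genes held by other lists this list no longer passed (adjusted p = 0.86). Lcn2, Mt1 and Mt2 are also in the acute-phase list.

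Changes in energy metabolism were smaller and most turned with scaling. Of 76 oxidative phosphorylation genes 44 rose and none fell with TMM (median 0.29), whereas 3 rose and 61 fell with total-count scaling (median -0.38). Cycs, cytochrome c, rose by 1.95 ± 0.11 and Atp5d, a subunit of ATP synthase, by 1.04 ± 0.14. The list was close to the camera threshold (adjusted p = 0.042, and 0.69 with an estimated correlation) and lost the call without saline replicate 1 (0.078), LPS replicate 1 (0.063) or LPS replicate 2 (0.11), and with upper-quartile factors (0.22), total-count scaling (0.53) or a stricter expression filter (0.054). Of 25 TCA cycle genes 12 rose and 3 fell (median 0.27, camera adjusted p = 0.49), against 1 and 18 with total-count scaling. Idh1 fell by 1.51 ± 0.27 and Mdh2 rose by 0.96 ± 0.12. In the glycolysis and hypoxia list 17 of 28 rose and 5 fell (18 and 6 adjusted over the list alone; median 0.57, camera adjusted p = 0.0012, and 0.27 with an estimated correlation), against 11 and 13 with total-count scaling. Pfkfb3 and Hk2, which promote glycolytic flux, rose by 3.57 ± 0.17 and 3.15 ± 0.17, and Pdk1 fell by 1.30 ± 0.24.

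Stress genes included large single changes. Of 23 antioxidant genes 17 rose and none fell (18 adjusted over the list alone; median 0.69, camera adjusted p = 9.5e-07, and 0.30 with an estimated correlation), against 9 and 6 with total-count scaling. Slc7a11, the cystine importer, rose by 8.10 ± 0.32, Srxn1 by 4.06 ± 0.14 and Sod2, the mitochondrial superoxide dismutase, by 3.08 ± 0.12. Of 26 unfolded protein and heat shock genes 15 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.59, camera adjusted p = 0.0032, and 0.27 with an estimated correlation), against 9 and 11 with total-count scaling. Bag3 rose by 2.09 ± 0.11 and Atf4 by 1.98 ± 0.11, whereas Ddit3, the stress factor CHOP, fell by 1.08 ± 0.15. Of 42 cytosolic ribosomal protein genes 39 rose and none fell (40 adjusted over the list alone; median 0.55, camera adjusted p = 0.00024, and 0.43 with an estimated correlation), whereas 2 rose and 12 fell with total-count scaling, under which the list no longer passed camera (adjusted p = 0.28). Rps20 rose by 0.96 ± 0.10, and Rpl38 by 0.72 ± 0.11 with TMM but by 0.05 with total-count scaling, which was not a call (adjusted p = 0.68).

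Of 30 cell cycle genes 16 fell and 4 rose (median -1.15), against 23 and 2 with total-count scaling (median -1.81). The list missed the camera threshold (adjusted p = 0.091, 0.43 with an estimated correlation) but passed with limma-voom (0.034). Mcm3, of the replicative helicase, fell by 1.81 ± 0.24, while Pcna and Tpx2 rose by 1.99 ± 0.13 and 2.13 ± 0.33. Genes of the circadian clock moved apart, with 8 of 19 rising and 7 falling (median 0.22, camera adjusted p = 0.66), against 6 and 11 with total-count scaling. Nfil3 and Arntl, the gene of BMAL1, rose by 5.37 ± 0.17 and 3.03 ± 0.26, and the PAR bZIP genes Hlf, Tef and Dbp fell by 2.60 ± 0.22, 1.98 ± 0.14 and 1.48 ± 0.23, as did Per3 by 2.40 ± 0.16.

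Markers of other cell types were measured alongside. All 16 measured neutrophil markers rose, with a median of 6.04 (camera adjusted p = 2.2e-17, and 0.010 with an estimated correlation). The list held 22 genes, and those near 0 in saline were in the deposited counts only where LPS raised them. This count and median are thus partly set by that filter. S100a8 rose by 8.70 ± 0.26, Ngp, a granule protein gene, had 1 count in saline and 1901 in LPS, a ratio of 2837 (95% counting interval 508.5 to 112100), and Cxcr2 went from 0 to 236 counts, at least 117.4-fold higher. All 5 erythroid genes rose (median 0.98, camera adjusted p = 0.014, and 0.32 with an estimated correlation), with 4 called at total-count scaling, where the list did not pass camera (adjusted p = 0.084). Hbb-bs and Hba-a1, which have near-identical copies, rose by 0.98 ± 0.10 and 0.98 ± 0.12. Of 21 monocyte and macrophage markers 7 rose and 6 fell (8 and 6 adjusted over the list alone; median 0.07, camera adjusted p = 0.48), against 4 and 12 with total-count scaling. Ly6c2, of inflammatory monocytes, rose by 3.80 ± 0.30 and Cd14 by 3.60 ± 0.14, whereas Cx3cr1 fell by 3.29 ± 0.24 and Csf1r by 1.22 ± 0.16. Of 12 lymphocyte markers 5 rose and 1 fell (median 1.10, camera adjusted p = 0.11, and 0.025 with total-count scaling). Only 13 of the 23 listed lymphocyte genes were in the deposited counts, so the same filter bears on this count and median. It also bears on other lists with missing members, such as acute-phase genes (27 of 30 in the counts) and coagulation genes (21 of 26). Gzmb and Gzma, of cytotoxic granules, rose by 5.01 ± 0.27 and 2.51 ± 0.36, and Ighm fell by 1.38 ± 0.22.

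Of 20 stromal, capsule and mural markers 11 fell and 2 rose (11 and 3 adjusted over the list alone; median -0.62, camera adjusted p = 0.022, and 0.38 with an estimated correlation), and none was called higher with total-count scaling. Col1a1 fell by 1.83 ± 0.14, Col3a1 by 1.25 ± 0.15 and Tcf21 by 1.51 ± 0.21. Of 11 Schwann and glial markers 5 fell and 1, Gfap, rose by 1.69 ± 0.39, while Sox10 fell by 3.76 ± 0.79 (8 lower and 1 higher with total-count scaling, median -0.57, camera adjusted p = 0.36). Of 16 adipocyte markers 5 fell and 1 rose (10 and 1 with total-count scaling, median -0.77, camera adjusted p = 0.18, 0.041 without LPS replicate 3 and 0.024 with limma-voom). Plin1 fell by 1.18 ± 0.22 and Pnpla2, a triglyceride lipase, rose by 0.98 ± 0.10. Fat cell transcripts varied widely between LPS libraries: Adipoq, chosen after its values were seen, was at 2.404, 15.03 and 40.9 CPM in LPS replicates 1, 2 and 3 and at 37.1, 33.6 and 26.3 CPM in saline replicates 1, 2 and 3, with a fall that was not called (adjusted p = 0.47) except without LPS replicate 3 (0.024) and with limma-voom (0.020). Neither measured platelet marker was called, with Pf4 at 0.39 ± 0.18 and Itga2b at 0.40 ± 0.33 (both below 0 with total-count scaling). No kidney tubule marker was measured, and among 4 liver markers 1, Ahsg, was called lower at -0.82 ± 0.33, a call absent when adjusted over the list alone or with DESeq2 (adjusted p = 0.074) and lost without saline replicate 1, 2 or 3 or LPS replicate 3 (adjusted p 0.058, 0.10, 0.085 and 0.18).

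**Figure D3:**
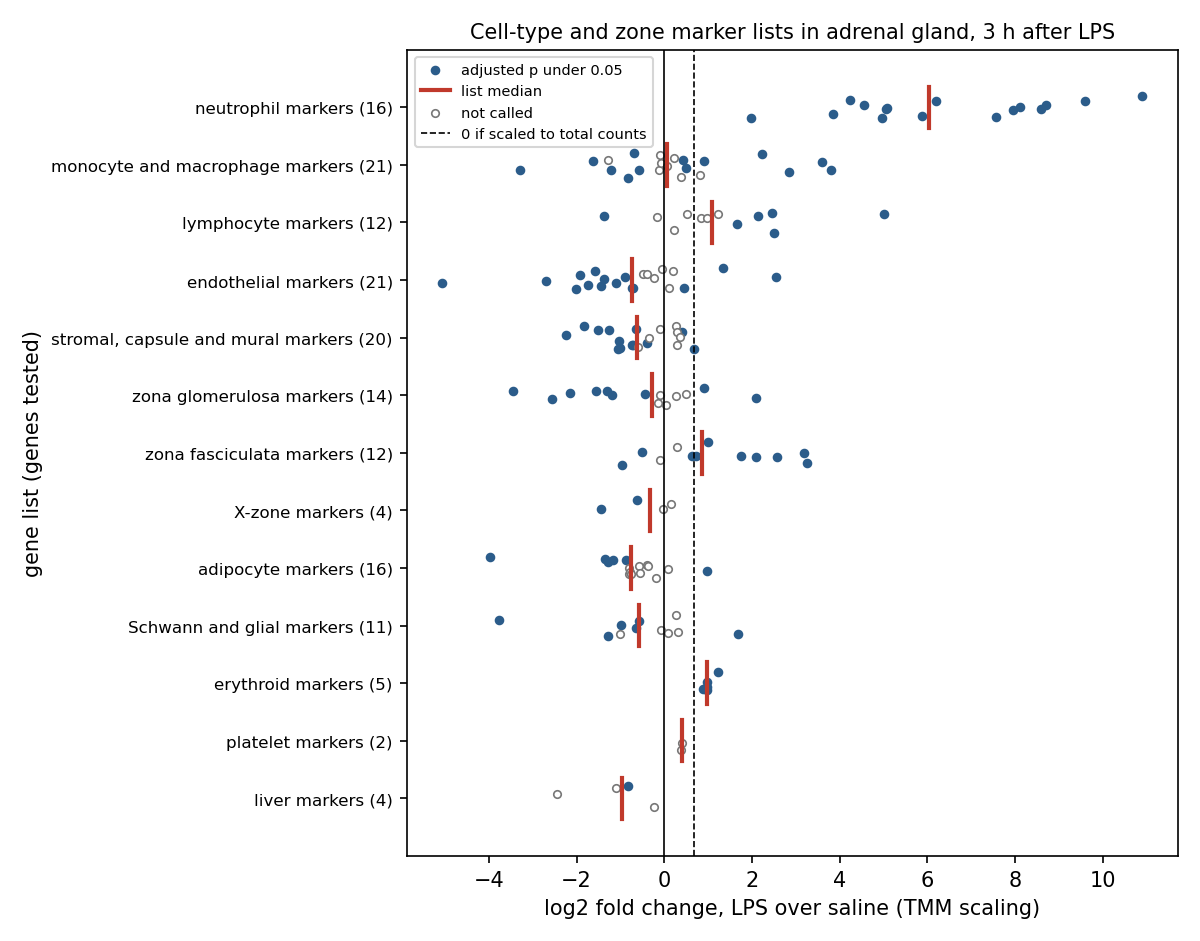
Log2 fold change of LPS over saline (x axis) for each tested member of 13 cell-type and zone marker lists (rows, with the number of genes tested), drawn as in the plot of the process lists, with red bars for medians and a dashed line where 0 lies with total-count scaling. All 16 neutrophil markers lie above 0, with a median of 6.04, whereas endothelial and stromal markers have medians of -0.74 and -0.62.

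Of the 38 lists, 36 had enough measured members to be tested, 24 passed camera (22 higher and 2 lower), and 11 passed with an estimated correlation: cytokines, chemokines, NF-kB, interferon-stimulated, acute-phase, LPS recognition, endothelial activation, coagulation, glucocorticoid-responsive, apoptosis and neutrophil genes. Counts adjusted over the list alone equalled those over all genes for the other lists among these 38 for which no second count is given, with antigen presentation at 20 higher and 2 lower.

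The authors' deposited table also holds their own comparison of the groups. With a dispersion per gene, the authors' deposited table called 4144 genes higher and 4314 lower, and with a common dispersion 3772 higher and 4394 lower. Against the gene-wise calls of the authors' deposited table, 4117 of the 15248 genes tested here were higher and 4218 lower in both. Of the same genes 0 had opposite calls, 177 were called only here and 87 only by the authors. The authors' calls among genes removed by the filter here are not in these counts. Across the 15248 genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson r of 0.9999. Both comparisons rest on the same libraries, so close agreement was to be foreseen and is no independent support for the calls.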

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

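All alternatives here were fixed before the data file was opened. For the counts of genes scaling mattered most: with total counts only, 1973 genes were higher and 8992 lower (1285 and 5610 by at least 2-fold), and 236 genes called higher with TMM were called lower. How much of that shift the share of counts in induced genes accounts for was not tested. The other alternatives left the 4 gene counts within 1.5 times and turned no call. Leaving out 1 library gave 3696 to 4101 genes higher, 3710 to 4072 lower, 2195 to 2318 higher and 2411 to 2541 lower by at least 2-fold, and 23 to 25 lists past camera. With the replicate block 4223 genes were higher and 4358 lower, 2263 and 2602 by at least 2-fold, and 23 lists passed; the oxidative phosphorylation list lost its call (adjusted p = 0.062). Same-numbered samples deviated together by correlations of -0.013, 0.0069 and 0.069, and not every sample correlated best with its own number. No pairing by number was seen, but 3 libraries per group cannot exclude a weak one. With an estimated correlation 11 lists passed in place of 24. The lists that lost the call had estimated correlations of 0.023 (endothelial markers) or more, above the preset 0.01. The adjusted p also rose where the estimate was below the preset: for cytokines (-0.017) from 5.9e-31 to 0.0037, and for coagulation (-0.0057) from 5.6e-12 to 0.010. For those 2 lists these values argue against a higher correlation between genes as the cause. The cause of the lost calls was not tested. By fry, which asks of each list alone whether it moved, 32 passed (26 higher and 6 lower), among them the cell cycle (adjusted p = 0.0065), clock (0.0097) and chromaffin (0.013) lists that camera did not call. The LPS minus saline difference in the share of the 20 most abundant genes, 2.09 percentage points, was 4.80 without mitochondrially encoded genes and 6.43 for the 100 most abundant genes, and 1.74 to 2.41 without 1 library.

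Among the genes named in the text, directions that turned with total counts were those of Th (-0.0147), Flt1 (-0.23), Pf4 (-0.28) and Itga2b (-0.26), all without a call there, and by camera those of the TCA cycle list (median minus that of all genes 0.31) and the oxidative phosphorylation list (0.32), both at adjusted p = 0.53. The steroidogenesis list turned without shared genes (0.34, adjusted p = 0.91; its median and its test differ in sign). The cholesterol uptake and storage list, never past a threshold, turned with fry (-0.0773), limma-voom (-0.0694), without saline replicate 3 (-0.1176) and without LPS replicate 2 (0.0186), within a range of -0.1256 to 0.0311 over the libraries left out. The cause of these turns was not tested. Depth limits genes with few counts in a group, whose folds are bounds or wide intervals.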

Other observations

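The lists and genes of the first 2 paragraphs, and the tests on neutrophil and endothelial markers and on neighbours split by overlap or by their own induction, were chosen only after their values were seen. The list tests of the first 2 paragraphs therefore reuse the values that led to the lists, and their p-values are no independent support. The comparisons of downstream, upstream and distant neighbours, and of sample splits, were written before they were run. Iron handling genes changed at several steps. Of 19 genes in a list of iron and haem handling 10 rose and 4 fell (camera adjusted p = 0.036 over 3 such lists; adjusted p = 0.22 with an estimated correlation), against 8 and 8 with total-count scaling. Hamp, encoding the iron-regulating hormone hepcidin, had 3 counts in saline and 516 in LPS, a ratio of 256.6 (95% counting interval 87.33 to 1249), and Slc40a1, encoding the iron exporter that hepcidin degrades, fell by 4.08 ± 0.24. Steap4, a metalloreductase, rose by 4.28 ± 0.19, Alas1, the first enzyme of haem synthesis, by 1.94 ± 0.15, and the ferritin light chain gene Ftl1 by 1.31 ± 0.10.

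Of 25 hedgehog and Wnt signalling genes 14 fell and 4 rose (15 and 4 adjusted over the list alone, 18 and 2 with total-count scaling, median -1.05; camera adjusted p = 0.0029; adjusted p = 0.13 with an estimated correlation). The receptor genes Fzd2 and Gas1 fell by 4.11 ± 0.43 and 3.51 ± 0.25, beside Shh and Wnt4, while Gli3 rose by 1.61 ± 0.21. Of 16 base excision repair genes 7 fell and 2 rose (7 and 3 adjusted over the list alone, camera adjusted p = 0.036; adjusted p = 0.13 with an estimated correlation), and 13 fell and none rose with total-count scaling; the DNA glycosylase genes Nthl1, Mutyh and Ogg1 fell by 4.14 ± 0.43, 4.01 ± 0.43 and 1.73 ± 0.24. Among 340 zinc finger genes with a Zfp symbol 159 fell and 36 rose, with a median of -0.62 against -0.03 for other genes, a difference that was not tested. With total-count scaling the median of these 340 genes was -1.29.

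Neutrophil markers rose together. More blood of unchanged make-up in the LPS glands, with unchanged transcript levels per blood cell, is argued against for the measured markers. The neutrophil median exceeded the erythroid median by 5.06 on the log2 scale (6.04 against 0.98). A two-sided permutation test gave p = 0.0018 but treats genes as independent, which they are not. The lowest neutrophil marker, at 1.97, lay above the highest erythroid one, at 1.23. Only 16 of the 22 listed neutrophil markers were in the deposited counts, and the loss of low ones may widen both gaps. Induction of these genes within blood cells was not tested. Neutrophils present in the LPS glands, inside vessels or in tissue, and induction of the same genes in cells of the gland cannot be told apart. All 8 granule and receptor genes (Ngp, Camp, Ltf, Mmp8, Retnlg, Cd177, Cxcr2, Csf3r) were called higher, but so were all 16 members of the list, so that count could not have come out otherwise, and Ltf lost its call without LPS replicate 1 (adjusted p = 0.0501). The 8 genes rose by a median 0.47 less than the other 8 members (a difference of -0.47; permutation p = 0.88), and bulk RNA holds no cell identity.

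Of the 21 endothelial markers 12 fell and 3 rose, and the list passed camera but not with an estimated correlation (adjusted p = 0.19). Fewer endothelial cells in the LPS glands would lower the markers by about 1 factor, but for 11 of the 21 the 95% interval left out the list median, and Cdh5 and Robo4 were called higher under all 5 scalings. The choice of scaling between libraries cannot be told apart from a fall in absolute level. A scaling moves all genes alike, and none of the 5 tried moved them up by enough to bring the list median to 0. The list median was at most -0.72 and at least -1.41. The list median minus that of all genes, -0.704 with TMM, is left nearly unchanged by a scaling. The fall relative to the bulk of genes therefore does not rest on that choice. A change of endothelial transcript levels with LPS stays open as a hypothesis that was not tested separately, as does a smaller loss of cells beneath it.

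Genes beside strongly induced genes rose in part, over 209 induced genes (at least 20 CPM in LPS and a log2 change of 4). Neighbours within 5 kb downstream had a median below that of upstream ones (difference -1.58, interval -3.85 to 0.31, permutation p = 0.0093), and upstream neighbours stood 1.92 above genes with no induced gene within 100 kb (permutation p = 0.0005, the smallest that 2000 draws give). Both differences were partly built in: 5 of the 27 upstream neighbours and 1 of the 42 downstream were induced genes themselves, and without these the differences were -0.25 (interval -2.08 to 0.59, permutation p = 0.58) and 0.555 (interval -0.04 to 2.39, permutation p = 0.028). In addition 13 upstream neighbours overlapped their induced gene and stood 4.22 above distant genes (permutation p = 0.0005). A further 13 neighbours lay inside or around an induced gene, with a median of 3.65. Both groups include genes that are induced themselves. Without overlap the excess over distant genes was 0.21 upstream (permutation p = 0.47, and 0.04 without induced neighbours, permutation p = 0.91) and 0.21 downstream (permutation p = 0.33), with downstream minus upstream at -0.0052 (permutation p = 0.97). The rule for reading the tests, which took the first difference to speak against reads running past the 3′ end of the induced gene, was changed once the overlaps were seen. Such reads, shared regulation of the neighbourhood and reads shared where the 2 genes overlap cannot be told apart, given an unstated strand setting and 12 upstream neighbours with neither overlap nor induction.

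The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 with the highest value for each count: 4198 genes higher, 4314 lower, 2277 and 2574 by at least 2-fold, and 24 lists past camera. The highest of the other splits by edgeR was 0 for each count of genes, with at most 220 genes at an unadjusted p under 0.05, and 22 for the lists. Every other split puts saline and LPS libraries in both groups, so the LPS difference widens the spread within groups. The 0 gene calls could therefore hardly have come out otherwise. The 13 to 22 lists past camera there still carry part of the LPS difference. These splits cannot show how many genes or lists would be called without LPS.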
